A study of Mus musculus with 11 samples.

How the data were processed

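The deposited table of TPM (length-scaled transcript shares) of the authors was used as given. It held 56980 genes in 11 libraries, each with the same sum. Per the labels' protocols, total RNA was taken with TRIzol from sorted cells, checked for quality, made into Illumina libraries of about 300.0 bp fragments with 15 PCR cycles, and read as pairs of 150 bp on a NovaSeq. Per the submitters' processing notes, reads were trimmed with fastp, aligned with HISAT2 to GRCm39 and quantified with StringTie, whose versions are not given in the sources used here. Reads and counts were not used here. The titles of the samples name both muscle and spleen, while the cell type field names spleen, and the spleen was taken as the source. The column of a DP_3mo library carries a number that no title of this group has and a prefix that no other column has. It was assigned to the group by its name and is called DP_3mo unnumbered. Which replicate it was, and whether another library of the group was left out, stayed unknown. Sex, strain and animal identity were not analysed here.

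Genes with at least 1 TPM in at least 2 of the 11 libraries were kept, which left 15698. Values were transformed to log2(TPM + 1) and fitted with limma 3.58.1 in R 4.3.3 (a linear model on 4 groups, moderated by empirical Bayes with a mean-variance trend). The residual degrees of freedom were 7. All adjusted p-values of genes are limma p-values adjusted by Benjamini and Hochberg within a comparison, with 0.05 as the threshold. Where adjusted over the list alone, the adjustment ran over the tested members of 1 list. It did not correct across lists or comparisons, and a gene in several lists was adjusted in each. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again at an estimated correlation, and with the rotation test fry, all adjusted over 28 lists. By fry, which asks whether the members of a list move one way and not whether they do so more than other genes, 1 list passed for the sort at 24 months, 5 over both ages and 0 in each of the other 5 comparisons. Files were read with the R package data.table, version 1.17.8, and figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

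The groups, comparisons, lists and alternatives were chosen before the data were examined. The comparisons over both ages and over both sorts, the random block, the term for libraries with few genes, and the fits without these or without the libraries numbered 2 were added afterwards. Naming list members on the adjustment over the list alone was added afterwards as well. The 29 lists hold 485 genes, 38 of them in more than 1 list, and cover T cell states, signalling, metabolism, ageing and markers of other cells. The stromal and endothelial list had 2 tested members and was not tested as a list. Named genes were Pdcd1, Tigit, Cd4 and Il1r2 in each comparison, then genes with an adjusted p under 0.05 whose groups did not overlap and whose mean was at least 5 TPM in the higher group, by size of change. Then came up to 4 members of each list. Predicted genes, clones, immunoglobulin and T cell receptor segments and small RNAs were left out of the second set. Some list members are not reported here. The symbols Atp5f1a, Atp5f1b, Atp5f1c, Atp5po and Ahsp were not in the file, the first 4 being listed under older names, and for Aldoa and Atp5o the entry with the highest mean was used.

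Whether the replicate numbers pair the libraries was checked by correlating deviations from group means across genes, which are not independent replicates. At 24 months the same-numbered DP and DN libraries correlated at 0.316, 0.409 and 0.414, and the pair numbered 1 at 3 months at 0.267, while same-numbered libraries of different ages did not correlate in common (-0.142 to 0.479). Pair 1 at 3 months and pair 3 at 24 months were both made of libraries with few genes above 0. Such libraries also correlated across numbers and ages (DP_3mo 1 with DP_24mo 3 at 0.296, DN_3mo 1 with DN_24mo 3 at 0.287). The correlations thus do not tell a pairing by number from a shared state of libraries. The number was tried as a fixed block and as a random block with a consensus correlation of 0.445. For the sort comparisons and the interaction the fixed block was the number within an age, as was the random block throughout. For the age comparisons the fixed block was the number across both ages. In it DP_3mo unnumbered carried no weight, so DP_3mo 1 alone stood for DP cells at 3 months. Other alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 5 TPM. Further ones were median-of-ratios scaling, quantile normalization and rescaling without immunoglobulin, T cell receptor, mitochondrial, ribosomal and haemoglobin genes. The last were only the groups compared, array weights, no mean-variance trend, and each library left out. An alternative that needs counts could not be run, since the deposited file holds TPM.

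The procedure was tested on simulated data with normal noise of the residual spread of each gene and 200.0 changed genes. At 24 months it found 0, 8, 32 and 86% of genes changed by 1, 2, 3 and 5 on the log2 scale between the sorts. Of 70 genes called there, out of 15012, 7 were false calls. Over both ages it found 4, 34, 78 and 90%, with 8 false calls among 111 called genes out of 15018. For age in DP cells it found 2, 6, 42 and 74%, with 2 false calls among 64 called genes out of 14979. The naive and central memory list raised by 1 on the log2 scale was called in 19 or 20 of 20 draws in each of the 5 comparisons simulated. Lists left alone were called 1 to 4 times per comparison over these draws. The noise was drawn independently for each gene and library. It held neither the correlation of genes within a list nor the deviations shared by same-numbered libraries. The rates of calls and false calls therefore do not carry over to the real libraries. The interaction and age over both sorts were not simulated.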

Results

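Bulk RNA sequencing was compared between CD4 T cells sorted from mouse spleen as PD-1+TIGIT+ (double positive, DP) or PD-1-TIGIT- (double negative, DN), at 3 and 24 months of age. There were 2 DP and 3 DN libraries at 3 months and 3 of each at 24 months. The questions were which genes set DP cells apart from DN cells, which differed with age in each population, and how Il1r2, the gene of the interleukin-1 decoy receptor named in the series title, stood among them. Of 56980 listed genes, 15698 were tested with limma on log2(TPM + 1), a scale on which the fold changes of low genes are understated. TPM keep no record of depth, so the depth was unknown, and the labels do not say that the libraries came from separate animals, so the p-values measured only the spread between these samples, which may be technical. In each group 1 library (DP_3mo 1, DN_3mo 1, DP_24mo 3 and DN_24mo 3) listed few genes above 0, from 12446 to 15159, against 18430 to 21684 in the other 7. These 4 libraries held 5.63 to 8.61% of their TPM in mitochondrially encoded genes, against 1.52 to 3.74% in the other 7. They held less in immediate early and stress genes (0.159 to 0.213% against 0.510 to 1.29%) and in interferon-stimulated genes (0.0893 to 0.160% against 0.265 to 1.28%).

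At 24 months DP cells held more Pdcd1 and Tigit, which encode the receptors used for the sort, and more Il1r2 than DN cells in every library. Pdcd1 averaged 308 ± 218 TPM in DP and 13.8 ± 12.4 TPM in DN cells (mean ± SD, n = 3 each), Tigit 436 ± 215 and 24.3 ± 14.8 TPM, and Il1r2 328 ± 162 and 15.9 ± 11.7 TPM. The differences on the log2 scale were 4.49 (SE 1.06) for Pdcd1, 4.18 (SE 1.15) for Tigit and 4.59 (SE 0.89) for Il1r2. Cd4, the coreceptor of all sorted cells, overlapped between the groups, though DP exceeded DN within each of the 3 numbers (0.90, SE 0.59, limma adjusted p = 1.0). None of the other 3 genes passed over all genes (limma adjusted p = 0.285 for Pdcd1, 0.402 for Tigit and 0.153 for Il1r2), and each had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries can give. Il1r2 passed when adjusted over the list alone (adjusted p = 0.00249 among 16 interleukin-1 family members), a call that a pseudocount of 0.1 ended (0.0540, in a range of 3.73e-06 to 0.0540 over the alternatives). With the replicate number as a random block, an alternative added after the data were examined, all 3 genes passed over all genes (adjusted p = 0.00757 for Il1r2, 0.0234 for Pdcd1 and 0.0406 for Tigit). With the number as a fixed block none of them did (0.245 for Il1r2 and 0.286 for both others), and the gene count was 0 by limma. Over all alternatives these values ranged from 0.000883 to 0.899 for Il1r2 and from 0.00136 to 1 for both others.

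**Figure D1:**
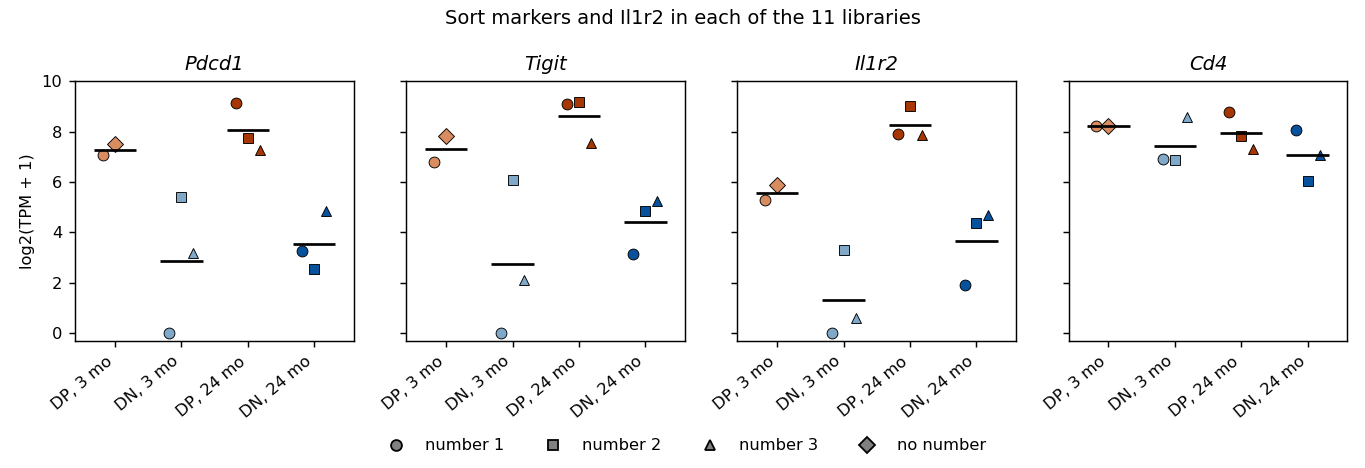
Each point is the log2(TPM + 1) of Pdcd1, Tigit, Il1r2 or Cd4 in 1 of the 11 libraries, by sort and age, with the replicate number as the shape and a bar at the group mean. The DP points of Pdcd1, Tigit and Il1r2 lay above the DN points at both ages, those of Cd4 overlapped, and DN_3mo 1 listed Pdcd1, Tigit and Il1r2 at 0.

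Genes of T cell inhibition, follicular help and regulation were higher together in DP than in DN cells at 24 months, and genes of naive cells were lower. These lists share members, so their results were not independent. Tox2, Cd200 and Batf counted in both the inhibitory and the follicular helper list, and Ctla4 in both the inhibitory and the regulatory list. Of 19 inhibitory receptors and exhaustion regulators, all had positive differences (median log2 1.69), and 8 rose and 11 did not pass when adjusted over the list alone. Among them was Lag3, an inhibitory receptor for MHC class II (3.58, SE 0.82; 22.0 ± 15.1 TPM in DP and 0.577 ± 0.255 TPM in DN). The transcription factor gene Tox2 (3.38, SE 0.88) was another, and so was Ctla4, which encodes a competitor of CD28 (2.32, SE 0.57). Each of these calls was kept under 25 of 26 alternatives, with limma p adjusted over the list alone up to 0.0542 for Lag3, 0.0624 for Tox2 and 0.0539 for Ctla4. The list passed camera (adjusted p = 3.27e-11), though not on the estimate of its own correlation (adjusted p = 0.173 with an estimated correlation). Of 20 follicular helper T cell genes, 19 had positive differences (median 1.73) and 12 rose when adjusted over the list alone, with camera adjusted p = 4.44e-18, which held at adjusted p = 0.0361 with an estimated correlation. Ascl2, a transcription factor of follicular helper cells, stood at 33.5, 16.9 and 19.9 TPM in the DP libraries, at 0.45 TPM in DN_24mo 1, and was listed at 0 in the other DN libraries (log2 4.37, SE 0.68). Angptl2, which encodes a secreted angiopoietin-like protein, stood at 123.5, 62.5 and 41.2 TPM in DP and at 3.4, 0.40 and 0 TPM in DN libraries (5.24, SE 0.83). All 20 regulatory T cell genes had positive differences (median 1.93) and 8 rose when adjusted over the list alone, among them Il10, the gene of a suppressive cytokine (4.05, SE 1.53), and Foxp3, the lineage factor of regulatory cells (3.06, SE 0.92). Over all genes neither passed (limma adjusted p = 0.805 for Il10 and 0.507 for Foxp3). Foxp3 stood at 223, 193 and 53.5 TPM in DP and at 75.1, 16.2 and 2.08 TPM in DN libraries, so the sorts overlapped across numbers while DP exceeded DN within each number. The Foxp3 call was kept under 21 of 26 alternatives and lost without DP_24mo 1 (0.0768), DP_24mo 2 (0.0552) or DN_24mo 3 (0.0651), with only the groups compared (0.0576) and without both libraries numbered 2 (0.0804). The Il10 call (adjusted p = 0.0481) was kept under 13 of 26. It was lost without DN_3mo 3 (0.0564), DP_24mo 1 (0.0781), DP_24mo 2 (0.170), DN_24mo 1 (0.151) or DN_24mo 3 (0.0651), and under 8 other alternatives (0.0543 to 0.155), among them all 3 other scalings. The list passed camera at 2.71e-11 (adjusted p = 0.179 with an estimated correlation).

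All 20 naive and central memory genes had negative differences in DP cells at 24 months (median log2 -1.58), and 7 fell when adjusted over the list alone. Satb1, a chromatin organizer of naive T cells, fell by 3.56 on the log2 scale (SE 1.03). The Satb1 call was kept under 19 of 26 alternatives and lost without DP_24mo 2 (0.0835), DP_24mo 3 (0.0594), DN_24mo 1 (0.0788) or DN_24mo 3 (0.0729), with a pseudocount of 0.1 (0.0604), no filter (0.0570) or no mean-variance trend (0.0564). The list passed camera at 7.99e-19 (adjusted p = 0.0681 with an estimated correlation). All 32 ribosomal protein genes were lower as well (median -0.69, camera adjusted p = 3.23e-20, adjusted p = 0.182 with an estimated correlation), with 0 past the threshold singly by limma adjusted over the list alone. Costimulatory receptors and ligands were higher (14 of 16 positive, median 0.94, camera adjusted p = 1.8e-06, adjusted p = 0.0939 with an estimated correlation). Of these, 3 rose when adjusted over the list alone, among them Tnfrsf4, the gene of OX40 (3.03, SE 0.68; 1424 ± 594 TPM in DP and 167 ± 59.0 TPM in DN). All 3 also belonged to the regulatory list (Tnfrsf4 and Tnfrsf18) or the follicular helper list (Tnfsf8). Glycolysis genes were higher (18 of 19, median 0.86, camera adjusted p = 1.27e-04, adjusted p = 0.257 with an estimated correlation). So were type 1 and cytotoxic genes (17 of 20, median 1.00, camera adjusted p = 3.58e-04, adjusted p = 0.264 with an estimated correlation). Of the latter, Cst7, a protease inhibitor gene of cytotoxic cells, was the 1 member that rose when adjusted over the list alone (2.02, SE 0.53, adjusted p = 0.0378). Over all genes Cst7 did not pass (limma adjusted p = 0.348). The Cst7 call was kept under 12 of 26 alternatives and lost without DP_3mo 1 (0.0582), DP_3mo unnumbered (0.0589), DN_3mo 1 (0.0554), DP_24mo 1 (0.256), DP_24mo 2 (0.107), DN_24mo 1 (0.0655) or DN_24mo 3 (0.114), and under each of the 3 other scalings (0.0712 to 0.174). No filter (0.0945), only the groups compared (0.111), no mean-variance trend (0.134) and leaving out both libraries numbered 2 (0.0952) ended it as well.

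Proliferation genes (median log2 0.77, camera adjusted p = 0.00764, adjusted p = 0.538 with an estimated correlation) and senescence genes (0.65, camera adjusted p = 0.00164, adjusted p = 0.333 with an estimated correlation) were higher in DP cells at 24 months. So were NF-kappaB pathway genes (0.61, camera adjusted p = 0.0305, adjusted p = 0.593 with an estimated correlation), while markers of CD8 T and NK cells were lower (-0.48, camera adjusted p = 0.0130, adjusted p = 0.333 with an estimated correlation). Each of these 4 calls was lost without single libraries, mostly with a median that stayed on its side of 0. The proliferation list did not pass without DP_24mo 2 (adjusted p = 0.308, median 0.52), DN_24mo 1 (0.131, 0.84) or DN_24mo 3 (0.0550, 0.65), and the senescence list did not without DP_24mo 2 (0.132, 0.65). The CD8 T and NK list was lost without DP_24mo 3 (0.139, -0.10) or DN_24mo 1 (0.131, with a median of 0.16 on the other side of 0). The NF-kappaB list did not pass without DP_24mo 1 (0.0983, 0.43), DP_24mo 2 (0.404, 0.37), DN_24mo 1 (0.0520, 0.55) or DN_24mo 3 (0.0550, 0.56), nor without both libraries numbered 2 (0.374, 0.29) or under any of the 3 other scalings (0.0607 to 0.0979, 0.42 to 0.47). In all, 12 of 28 tested lists passed camera and 1 with an estimated correlation, and the count was 18 without DP_24mo 3. By limma 0 single genes passed over all genes at 24 months (smallest adjusted p = 0.0652), and 803 had an unadjusted p under 0.05, against 784.9 expected by chance. Array weights, which set how much each library counts, were 2.97, 2.70 and 0.552 for DP_24mo 1 to 3. They were 3.97, 0.518 and 0.496 for DN_24mo 1 to 3. The fit with these weights, which also gave Il1r2 its lowest limma adjusted p (0.000883), thus leaned on DP_24mo 1, DP_24mo 2 and DN_24mo 1. The gene count was 1 without DP_3mo 1, DP_3mo unnumbered or DN_24mo 2 and 2 without DP_24mo 3 or DN_24mo 3, and it was 538 with array weights and 124 with the random block.

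At 3 months the sort separated the same marker genes. Pdcd1 stood at 133 and 180 TPM in the DP libraries and at 0, 41.4 and 8.21 TPM in the DN libraries (log2 4.41, SE 1.18). Tigit stood at 109 and 228 against 0, 66.9 and 3.34 TPM (4.57, SE 1.28). Il1r2 stood at 37.7 and 58.1 against 0, 8.92 and 0.54 TPM (4.27, SE 1.00). The value of 0 in all 3 genes belonged to DN_3mo 1, which listed 133 genes at 0 that held at least 5 TPM in every other library. None of the 3 passed over all genes (limma adjusted p = 0.420, 0.427 and 0.388), and the exact two-sided permutation p was 0.2 for each. Cd4 again overlapped (0.79, SE 0.66, limma adjusted p = 0.910). In the interleukin-1 family, Il1r2 and Casp1, the gene of the protease that matures interleukin-1 beta, rose when adjusted over the list alone (adjusted p = 0.0109 for each). Casp1 differed by 3.01 (SE 0.75, with 92.6 ± 22.9 TPM in DP and 11.2 ± 5.30 TPM in DN). Both calls were lost without DP_3mo 1 (0.0701 for Il1r2 and 0.134 for Casp1) or DP_3mo unnumbered (0.0855 for each), and over the alternatives the values ranged up to 0.133 for Il1r2 and 0.134 for Casp1.

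The list pattern at 3 months was led by all 20 naive and central memory genes, which were lower in DP cells (median log2 -1.56). Of them 8 fell when adjusted over the list alone (camera adjusted p = 3.86e-16, adjusted p = 0.193 with an estimated correlation). Satb1 fell by 5.65 on the log2 scale (SE 1.15; 0 and 36.2 TPM in DP, 395, 194 and 369 TPM in DN), and Ccr7, the gene of a lymph node homing receptor, fell by 2.19 (SE 0.56). The Satb1 call was kept under 24 of 26 alternatives, and the fit without DP_3mo 1 was among those that ended it. Follicular helper genes were higher (17 of 20, median 1.35, camera adjusted p = 4.26e-07, adjusted p = 0.220 with an estimated correlation), and 6 rose when adjusted over the list alone. Among these was Cxcr5, the receptor gene that guides T cells to B cell follicles (3.6, SE 1.01; 50.3 and 81.9 TPM in DP and 0, 10.7 and 12.4 TPM in DN). The Cxcr5 call was kept under 24 of 26 alternatives, and the fit without DP_3mo unnumbered was among those that ended it. All 20 regulatory T cell genes had positive differences (median 1.62, camera adjusted p = 6.04e-07, adjusted p = 0.366 with an estimated correlation), and 6 rose when adjusted over the list alone. Ikzf2, which encodes the transcription factor Helios, stood at 119.6 ± 0.66 TPM in DP and 10.6 ± 7.0 TPM in DN cells (3.65, SE 0.72). Inhibitory receptors and exhaustion regulators were higher (15 of 19, median 1.21, 3 rose when adjusted over the list alone, camera adjusted p = 2.52e-04, adjusted p = 0.474 with an estimated correlation). Costimulatory genes (median 1.19, camera adjusted p = 3.43e-04, adjusted p = 0.274 with an estimated correlation) were higher. So were senescence genes (1.20, camera adjusted p = 0.00293, adjusted p = 0.474 with an estimated correlation) and proliferation genes (0.82, camera adjusted p = 0.00754, adjusted p = 0.702 with an estimated correlation). Ribosomal protein genes (-0.54, camera adjusted p = 5.11e-14, adjusted p = 0.366 with an estimated correlation) and CD8 T and NK markers (-1.04, camera adjusted p = 3.04e-04, adjusted p = 0.274 with an estimated correlation) were lower.

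Of these 9 lists at 3 months, 0 passed with an estimated correlation, and 4 were lost without DP_3mo unnumbered: the inhibitory list (camera adjusted p = 0.498), the regulatory list (0.242), the proliferation list (0.903) and the senescence list (0.186). The senescence list was also lost without DN_3mo 1 (0.0585) or DN_3mo 3 (0.0714). A pseudocount of 0.1 (0.0555) and a filter of 5 TPM (0.0791) each ended the call of the proliferation list. With the replicate number as a fixed block, which left 1 pair at this age, the inhibitory list (0.351), the proliferation list (0.518) and the CD8 T and NK list (0.0638) did not pass. By limma 0 single genes passed at 3 months (smallest adjusted p = 0.169), and 1009 had an unadjusted p under 0.05. The gene count was 3 without DP_3mo unnumbered and 2 without DN_3mo 1, and it was 7 with the random block.

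**Figure D2:**
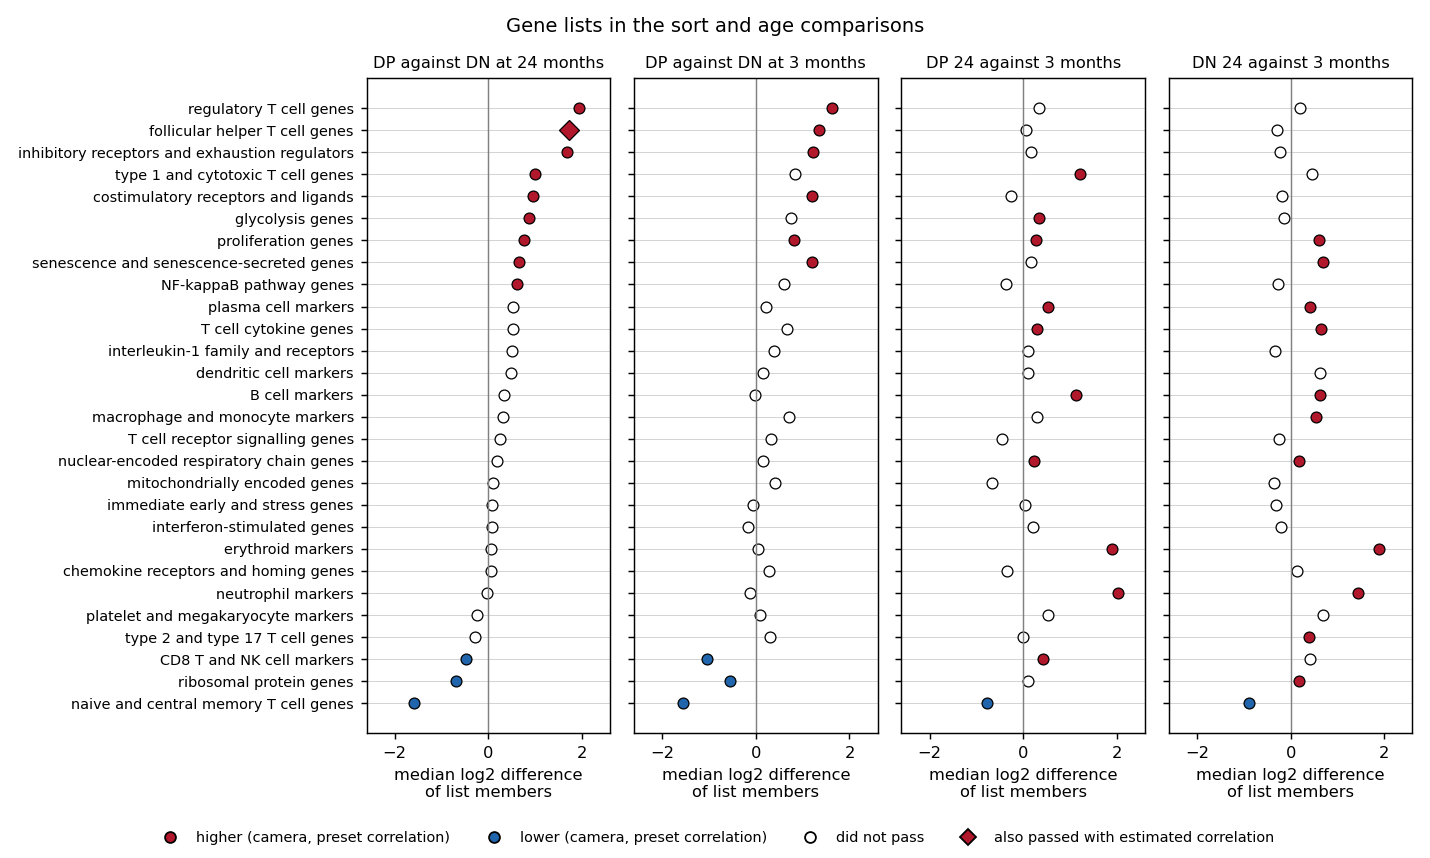
Each point is the median log2 difference of the tested members of 1 of 28 gene lists, in 4 comparisons, filled red or blue where camera with a preset correlation passed and open where it did not. Lists of regulatory, follicular helper and inhibitory genes lay highest and naive genes lowest in both sort comparisons, and the follicular helper list at 24 months, the diamond, also passed with an estimated correlation.

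Over both ages together, a comparison added after the data were examined because no single age called a gene, 59 genes differed between DP and DN cells (50 higher and 9 lower in DP; limma adjusted p down to 0.00332). All 59 had the same sign at both ages, and in 55 of them the 5 DP libraries did not overlap with the 6 DN libraries, but choosing genes on the mean of the ages favoured both. Of the 59, 11 belonged to a preset list. Ly6c1, which encodes a surface antigen of naive and memory lymphocytes, fell by 7.13 on the log2 scale (SE 0.75, adjusted p = 0.00332): the DN libraries held 298 to 902 TPM, and the DP libraries 0, 18.9, 9.99, 6.57 and 0 TPM. Sccpdh, an oxidoreductase-like gene, was higher (4.74, SE 0.53, adjusted p = 0.00335), with 22.6 to 47.7 TPM in the 5 DP libraries and at most 1.52 TPM in the 6 DN libraries. Angptl2 (4.85, SE 0.62) and Ascl2 (3.92, SE 0.51) were called at adjusted p = 0.00882 each, and Rgs16, a regulator of G protein signalling, at 0.0115 (3.96, SE 0.56; 58.0 to 223 TPM in DP and 1.66 to 13.7 TPM in DN). The sort genes Pdcd1 (4.45, SE 0.79, adjusted p = 0.0408) and Tigit (4.38, SE 0.86, adjusted p = 0.0488) were called. So was Il1r2 (4.43, SE 0.67, adjusted p = 0.0164), with all 5 DP libraries above all 6 DN libraries in each. Further genes higher in DP cells were Sostdc1, which encodes a secreted antagonist of bone morphogenetic proteins (4.44, SE 0.80), Tox (2.03, SE 0.38), Ctla4 (2.41, SE 0.43), Ikzf2 (2.92, SE 0.48) and Maf, a transcription factor gene of follicular helper cells (2.46, SE 0.43). Lower in DP cells were Pdlim4 (-4.72, SE 0.69) and Pdlim1 (-2.18, SE 0.40), both cytoskeletal adaptor genes, Satb1 (-4.60, SE 0.77) and Klf2, which keeps naive T cells quiescent and circulating (-1.40, SE 0.28).

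The count of 59 genes moved with single libraries. It was 42 without DN_3mo 1, 47 without DN_3mo 2 and 39 without DN_24mo 2. It was 4 without DP_3mo 1, 7 without DP_3mo unnumbered, and 16 without DN_3mo 3. It was 10 without DP_24mo 1 or DP_24mo 2, 29 without DP_24mo 3, 11 without DN_24mo 1 and 26 without DN_24mo 3. Ly6c1 and Sccpdh were called in all 11 of these fits, Ascl2, Gstt3 and Rgs16 in 10, Angptl2, Ces2c and Pdlim4 in 9, and Il1r2 in 7. The calls of Sostdc1 and Satb1 were kept in 4, that of Pdcd1 in 3, that of Pdlim1 in 2 and those of Tigit and Klf2 in 1. With the replicate number as a fixed block, in which libraries without a partner do not count, 0 genes passed by limma, and with the random block 462 did, all 59 among them. With array weights, which were highest for DP_24mo 1, DP_24mo 2 and DN_24mo 1, 318 genes passed. With a term for the 4 libraries with few genes 248 did, and all 59 were again among them in each. A pseudocount of 0.1 gave 0 genes, no filter on low values 14, median-of-ratios scaling 27 (13 higher and 14 lower), and quantile normalization 64 (40 higher and 24 lower, 39 of them shared). Leaving out the 4 libraries with few genes left DP_3mo unnumbered alone to stand for DP cells at 3 months. With only 7 libraries kept, calls can be lost from their number alone. That fit therefore does not show whether the calls depend on these libraries. Without both 24-month libraries numbered 2 there were 4 genes. Of 28 lists, 12 passed camera and 2 with an estimated correlation. These were the naive list (median log2 -1.39, camera adjusted p = 2.85e-23, adjusted p = 0.0384 with an estimated correlation) and the follicular helper list (1.49, camera adjusted p = 4.16e-14, adjusted p = 0.0384 with an estimated correlation).

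**Figure D3:**
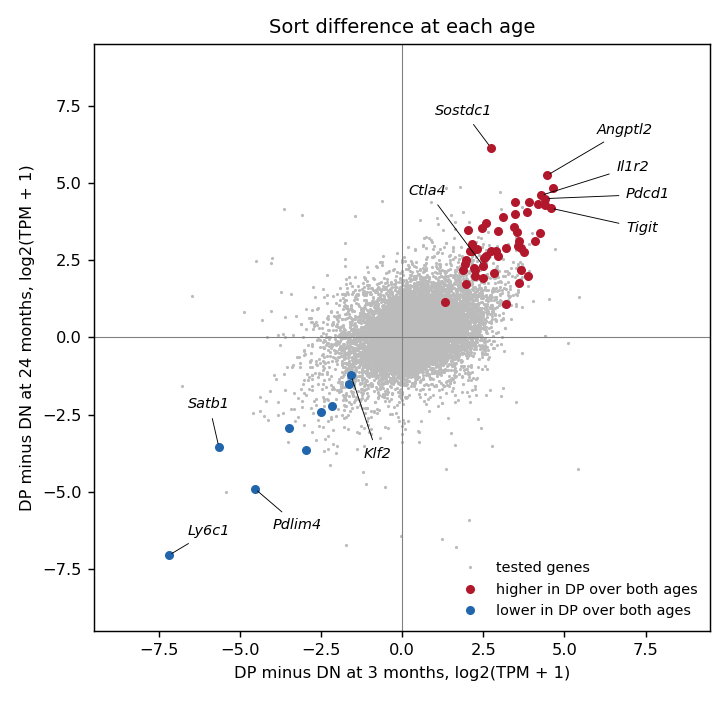
Each point is 1 of 15698 tested genes, with the DP minus DN difference of log2(TPM + 1) at 3 months on the horizontal and at 24 months on the vertical axis. The 50 genes higher and 9 genes lower in DP cells over both ages lay at the upper right and lower left, with Ly6c1 at -7.20 and -7.06.

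Across all 15698 genes the sort difference at 3 months and that at 24 months, which share no library, correlated with Pearson r 0.377 and Spearman rho 0.323. This is a relation across genes, which are not independent replicates, and 63.0% of them had the same sign. The r fell to 0.219 with the fixed block, and it was 0.292 to 0.407 with single libraries left out.

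With age, Il1r2 was higher in the DP libraries: 47.9 ± 14.4 TPM at 3 months (n = 2) and 328 ± 162 TPM at 24 months (n = 3), with all 3 older libraries above both younger ones. The log2 difference of 2.68 (SE 1.00) did not pass over all genes (limma adjusted p = 0.972) nor over the list alone (0.286), and the exact two-sided permutation p was 0.1, the smallest that 3 against 2 libraries can give. In DN cells Il1r2 stood at 0, 8.92 and 0.54 TPM at 3 months and at 2.76, 19.8 and 25.1 TPM at 24 months (2.35, SE 0.89, limma adjusted p = 1, exact permutation p = 0.2). Over both sorts, a comparison added after the data were examined, Il1r2 rose by 2.52 on the log2 scale (SE 0.67, adjusted p = 0.0345 adjusted over the list alone and 0.784 over all genes). The call over the list alone was kept without DN_3mo 2 or DN_24mo 1 and lost without any of the other 9 libraries (0.0576 to 0.195 without DP_24mo 3 and DP_3mo 1), and over all alternatives it ranged up to 0.592. Pdcd1 (0.77, SE 1.18, limma adjusted p = 0.975) and Tigit (1.30, SE 1.28, limma adjusted p = 0.972) of the DP libraries overlapped between the ages, and so did Cd4 (-0.28, SE 0.66, limma adjusted p = 0.988).

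Among gene lists in DP cells, type 1 and cytotoxic T cell genes were higher at 24 months (17 of 20 positive, median log2 1.21, camera adjusted p = 2.83e-04, adjusted p = 0.561 with an estimated correlation). By limma 0 members passed over the list alone. Ccl3, a chemokine gene of this list, differed by 2.47 (SE 1.38). Nuclear-encoded respiratory chain genes were higher by a small margin (23 of 27, median 0.23, camera adjusted p = 4.93e-04, adjusted p = 0.451 with an estimated correlation). B cell markers were higher (15 of 16, median 1.13, camera adjusted p = 7.54e-05, adjusted p = 0.561 with an estimated correlation). These are markers of other cells, and held 0.160 and 0.169% of TPM in DP libraries at 3 months and 0.842, 0.615 and 0.246% at 24 months. In DN libraries their share ran from 0.0757 to 0.337% at 3 months and from 0.0924 to 0.707% at 24 months. Whether B cells or their RNA in the sorted samples brought the difference was not tested. Igkc, the immunoglobulin kappa constant gene, stood at 255 and 237 TPM at 3 months and 3379, 2769 and 533 TPM at 24 months (2.79, SE 1.14). Plasma cell markers were higher too (9 of 10, median 0.54, camera adjusted p = 7.06e-04, adjusted p = 0.561 with an estimated correlation). Ighg2c, an immunoglobulin heavy chain constant gene, was listed at 0 and 0.78 TPM at 3 months and at 38.3, 18.1 and 24.1 TPM at 24 months. It rose when adjusted over the list alone (4.32, SE 1.24, adjusted p = 0.0378). That Ighg2c call was lost without DP_3mo 1 (0.334), DP_3mo unnumbered (0.115), DP_24mo 1 (0.108), DP_24mo 2 (0.0536) or any of DN_3mo 1, 2 and 3 (0.0501, 0.0554 and 0.0532), and over the alternatives it ranged up to 0.334. The calls of these 4 lists were kept with each library left out. Naive and central memory genes were lower (18 of 20 negative, median -0.78, camera adjusted p = 0.00214, adjusted p = 0.561 with an estimated correlation). This call was lost without DP_3mo unnumbered (median -0.98) and with the number across both ages as a fixed block (median -0.54). Both fits left DP_3mo 1 alone to stand for DP cells at 3 months.

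Neutrophil markers (all 15 positive, median log2 2.02, camera adjusted p = 3.74e-05, adjusted p = 0.561 with an estimated correlation) and erythroid markers (all 11 positive, median 1.90, camera adjusted p = 7.54e-05, adjusted p = 0.561 with an estimated correlation) were higher at 24 months. Both rested on a single DP library. DP_24mo 2 held 0.499% of its TPM in neutrophil and 3.17% in erythroid markers, its DN counterpart DN_24mo 2 held 0.711% and 4.37%, and no other library exceeded 0.0655% and 0.0865%. Without DP_24mo 2 the medians were 0.52 and -0.12 (adjusted p = 0.266 and 0.464). CD8 T and NK markers (0.43, camera adjusted p = 0.0110), glycolysis (0.33, 0.0214), proliferation (0.26, 0.0300) and T cell cytokine genes (0.30, 0.0420) completed the 11 lists that passed, each with adjusted p = 0.561 with an estimated correlation. All 4 were lost without DP_24mo 2 (0.136, 0.102, 0.361 and 0.266) and without DP_3mo 1 (0.0580, 0.0571, 0.938 and 0.870), where the medians of proliferation (-0.37), cytokine (-0.27) and CD8 T and NK genes (-0.04) lay on the other side of 0. Without DP_24mo 2 those of cytokine (-0.16) and proliferation genes (-0.00) did. Also lost were the glycolysis list without DP_3mo unnumbered (0.0530) or DP_24mo 1 (0.0628), and the cytokine list without DP_24mo 1 (0.0628). Processing and model choices ended calls as well. With no filter the glycolysis (0.0620), proliferation (0.119) and cytokine lists (0.0924) did not pass, and with median-of-ratios scaling the proliferation (0.0614) and cytokine lists (0.0804) did not. The cytokine list was also lost with quantile normalization (0.136) and with the term for libraries with few genes (0.107, median -0.02), and the proliferation list with that term (0.0529) and with only the groups compared (0.0609). Without the 4 libraries with few genes the proliferation (0.303) and cytokine lists (0.388) did not pass, and without both libraries numbered 2 none of the 4 did (0.136, 0.0627, 0.286 and 0.286). The number of lists was 6 without DP_24mo 2, 17 without DP_3mo unnumbered and 19 without DP_24mo 3, 7 without both libraries numbered 2, and 17 with the fixed block. By limma 0 single genes passed in DP cells with age (smallest adjusted p = 0.319), and 622 had an unadjusted p under 0.05, against 784.9 expected by chance. The fixed block gave 2.

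**Figure D4:**
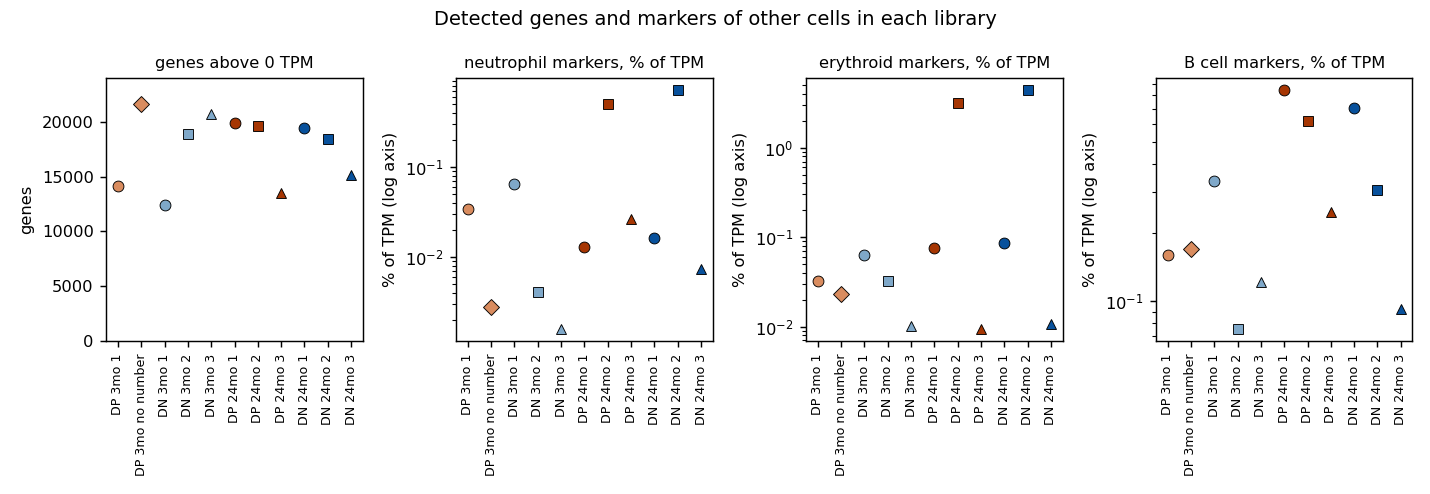
Each point is 1 of the 11 libraries, with the number of genes above 0 TPM in the first panel and the percent of TPM in neutrophil, erythroid and B cell markers, on log axes, in the others. DP_24mo 2 and DN_24mo 2 stand apart in neutrophil (0.499 and 0.711%) and erythroid markers (3.17 and 4.37%), and 4 libraries, 1 per group, list the fewest genes.

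In DN cells all 20 naive and central memory genes were lower at 24 than at 3 months (median log2 -0.89, camera adjusted p = 1.11e-05, adjusted p = 0.640 with an estimated correlation). Among them Klf3, a transcription factor gene of naive lymphocytes, stood at 388 ± 112 and 129 ± 80.2 TPM (-1.75, SE 0.49, n = 3 each), and did not pass over the list alone (adjusted p = 0.0672). The naive list passed with each library left out, whereas the other 11 lists that passed were all lost without DN_24mo 2 (adjusted p = 0.0704 to 0.983). These were the erythroid (median 1.88, camera adjusted p = 1.88e-05), neutrophil (1.44, 0.00106), proliferation (0.61, 0.00143), respiratory chain (0.19, 0.0105), B cell (0.63, 0.0182), macrophage (0.54, 0.0182), ribosomal protein (0.17, 0.0186), and plasma cell lists (0.42, 0.0230). The others were the senescence (0.70, 0.0342), type 2 and type 17 (0.40, 0.0398) and T cell cytokine lists (0.64, 0.0398). All were higher at 24 months, with adjusted p = 0.640 with an estimated correlation except for B cell markers (0.711) and ribosomal genes (0.754). Their direction depended on single libraries in 4 lists. The B cell median was -0.39 without DN_24mo 1 (adjusted p = 0.932), the cytokine (-0.14), senescence (-0.04) and ribosomal medians (-0.01) were negative without DN_3mo 1, and the ribosomal median was -0.04 without DN_24mo 2.

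The count of 12 lists in DN cells fell to 1 without DN_24mo 2, where the erythroid list had a median log2 difference of 0.29 (adjusted p = 0.714) and the neutrophil list 0.08 (0.932). It was 3 without DN_3mo 3, 6 without DN_24mo 1 and 19 without DN_24mo 3. Without DN_3mo 1 the type 2 and type 17 (0.351), senescence (0.415), T cell cytokine (0.784) and ribosomal lists (0.383) did not pass, and without DN_3mo 2 the B cell (0.143) and plasma cell lists (0.0889) did not. The count was 7 with no filter on low values or with median-of-ratios scaling. By limma 0 single genes passed in DN cells with age (smallest adjusted p = 1), and 388 had an unadjusted p under 0.05. The gene count was 2 without DN_3mo 1 or DN_24mo 3, 1 without DN_24mo 2, and 6 without the 4 libraries with few genes.

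The difference between the age change of DP and that of DN cells was tested directly. For Il1r2 it was 0.33 (SE 1.34, limma adjusted p = 1.00), so an age change that differed between the sorts was not shown, and for Pdcd1 and Tigit it was 0.08 (SE 1.59) and -0.39 (SE 1.72). By limma 0 genes passed (smallest adjusted p = 1.00), 215 had an unadjusted p under 0.05, and 0 of 28 lists passed camera (smallest adjusted p = 0.268, for follicular helper genes, 0.990 with an estimated correlation). With single libraries left out the list count was 7 without DP_24mo 3, 6 without DN_3mo 1, 5 without DP_3mo unnumbered, 4 without DN_24mo 2, 3 without DP_3mo 1 or DN_24mo 3, 2 without DP_24mo 2 and 1 without DN_3mo 2 or DN_24mo 1. Across 15698 genes the age changes of DP and DN cells, which share no library, correlated with Pearson r 0.260 and Spearman rho 0.265, and 61.3% had the same sign. Same-numbered DP and DN libraries of an age shared deviations, so the age changes of the sorts were not independent and an r above 0 does not show a shared age change. The correlation of age changes between DP and DN had an r of 0.137 without DN_24mo 2, 0.161 without DN_3mo 3 and 0.169 without DN_24mo 1. It was 0.0586 with the number across both ages as a fixed block. That block does not pair libraries within an age, and it left DP_3mo 1 alone to stand for DP cells at 3 months.

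The median difference of all tested genes was -0.23 for age in DP cells, 0.16 and 0.27 for the sort at 24 and 3 months, and -0.10 for age in DN cells on the log2 scale. Median-of-ratios scaling moved it to 0.10, 0, 0.00 and 0.10, and quantile normalization to -0.03, -0.02, -0.01 and -0.03. The medians of the sort and age lists named above as higher or lower in these 4 comparisons kept their sign under each of the 3 other scalings that could be applied to them.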

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

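The tests of Il1r2 and of the blood cell markers were chosen only after the result was seen. The age change of mt-Nd4l, a mitochondrially encoded subunit of respiratory complex I, differed between DP and DN cells by 7.81 on the log2 scale (SE 1.96). It passed by its list (adjusted p = 0.0179 adjusted over the list alone and limma adjusted p = 1.00 over all genes). It stood at 27.7 and 0 TPM in DP and at 47.9, 60.1 and 100.4 TPM in DN cells at 3 months, and at 102.2, 34.8 and 45.8 TPM and 0, 29.0 and 0 TPM at 24 months. The call was lost without DP_3mo unnumbered (0.187), DN_3mo 3 (0.0522), DP_24mo 1 (0.0505), DN_24mo 1 (0.0501) or DN_24mo 3 (0.0550), and with the fixed replicate block the value was 4.93 (0.473). It was also lost with no filter (0.0903) and without the 4 libraries with few genes (0.0508). mt-Nd4l was listed at 0 in DN_24mo 3, the library with the largest share of TPM in mitochondrially encoded genes (8.61%). A listed 0 may thus not mean an absent transcript, which was not tested. The list of mitochondrially encoded genes did not pass camera in this comparison. The cause of the difference was not tested.

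Il1r2 was higher in DP cells at 24 than at 3 months by 2.68 on the log2 scale. Neutrophil RNA was argued against, since at most 2.33% of Il1r2 in a 24-month DP library was accounted for by S100a8 at the ratio of the DN libraries rich in it. A larger share of regulatory T cells could not be told apart from a change within cells: Il1r2 exceeded the mean of the regulatory list by 2.32 (SE 1.19), and the list mean itself changed by 0.36 (SE 1.00), so the error kept it open. A biological difference with age stays open and was not tested.

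Neutrophil and red cell markers were higher at 24 months over both sorts, with a median of 1.74 on the log2 scale over 26 members. Without both libraries numbered 2 the median was 0.0681 (adjusted p = 0.502 for neutrophil and 0.452 for erythroid markers), so the pattern lay in these 2 libraries. They were chosen because they held the most of these markers, so leaving them out restated in part what prompted the test. A smaller share of T cell RNA was argued against, since these members stood 4.22 higher relative to 5 other marker lists in the libraries numbered 2 than in the other 24-month libraries. The size of 4.22 also draws on the values by which these libraries were chosen. Of the 5 lists, macrophage and monocyte markers were raised as well (median 1.84), below neutrophil (4.59) and erythroid markers (4.82). The remaining lists had medians from 0.0130 for B cell to 0.397 for dendritic cell markers. Whether whole blood cells or only their RNA brought these values, and how, was not tested and stays open.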

How the results depend on the processing

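Of 11535 gene values under the alternatives 10464 stayed the same, 524 were weaker, 7 stronger and 540 moved, and of 4396 list values 3963 stayed the same, 219 were weaker, 203 stronger and 11 moved. The same covers calls that were kept, but also genes without a call that stayed so or moved by at most 1 SE, and lists that stayed without one. These totals are therefore not the share of calls kept. Over both ages Tigit kept its call under 6 of 25 alternatives, Klf2 under 8, Pdcd1 under 11 and Il1r2 under 15, while Ly6c1 and Sccpdh kept it under 22. In 0 values of either set did a called gene or list pass in the opposite direction, though some medians of called lists crossed 0 without passing there. List tests were not run with array weights, without a trend or with the random block. An alternative on counts was not run, since counts were not used here. Where a cause is not named it was not tested.

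With a pseudocount of 0.1 the gene counts were 1 with age in DP cells, 1 for the sort at 3 months and 0 over both ages, and the correlations across genes were 0.307 for the sort and 0.183 for age. With a pseudocount of 5 there were 9 genes for the sort at 24 months and 1 at 3 months, and the correlations were 0.442 and 0.340. With no filter on low values 2 genes passed with age in DP cells, 2 for the sort at 3 months, 14 over both ages, 1 with age over both sorts and 1 for the interaction, and 7 lists with age in DN cells. The filter of 5 TPM gave 17 lists with age in DP cells. Median-of-ratios scaling gave 2 genes for the sort at 24 months, 27 over both ages and 7 lists with age in DN cells, and quantile normalization 4 genes for the sort at 24 months. With only the groups compared 1 gene passed for the sort at 24 months, and with no mean-variance trend 8 did. Array weights, which were highest for DP_24mo 1, DP_24mo 2 and DN_24mo 1, gave 538 genes for the sort at 24 months, 318 over both ages and a correlation of age changes of 0.411.

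The replicate block gave 2 genes with age in DP cells, 1 with age over both sorts and 0 for the sort over both ages, 17 lists with age in DP cells and 1 for the interaction, and a correlation of sort differences of 0.219. The correlation of age changes between DP and DN was 0.0586 with it. For the age comparisons this block tied equal numbers of both ages and did not pair libraries within an age. Besides the calls named beside their results, it ended those of T cell receptor signalling genes (0.144) and of Il1r2 over the list alone (0.0924) with age over both sorts, and no other call printed in the text. The replicate block as a random effect gave 124 genes for the sort at 24 months, 7 at 3 months and 462 over both ages, and correlations of 0.329 and 0.0783. The term for the 4 libraries with few genes gave 7 genes for the sort at 24 months and 248 over both ages. Leaving these libraries out kept DP_3mo unnumbered alone for DP cells at 3 months, so calls can be lost there from the number of libraries alone. With these 4 libraries left out there was 1 gene for the sort at 24 months, 6 with age in DN cells, 3 with age over both sorts, 1 for the interaction and 0 over both ages. There were 7 interaction lists and a correlation of age changes of 0.420. With both 24-month libraries numbered 2 left out there were 4 genes over both ages, 7 lists with age in DP cells, 1 in DN cells, 5 over both sorts and 1 for the interaction, and correlations of 0.329 and 0.164. The estimated inter-gene correlation left 0 lists with age in DP cells, 0 in DN cells, 0 over both sorts, 1 for the sort at 24 months, 0 at 3 months and 2 over both ages.

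With each library left out in turn, the gene counts were 0 to 0 with age in DP cells, 0 to 2 for the sort at 24 months, 0 to 3 at 3 months, and 0 to 2 with age in DN cells. They were 0 to 0 for the interaction, 4 to 47 for the sort over both ages and 0 to 1 with age over both sorts. The list counts were 6 to 19 with age in DP cells, 11 to 18 for the sort at 24 months, 7 to 13 at 3 months, and 1 to 19 with age in DN cells. They were 0 to 7 for the interaction, 11 to 15 over both ages and 10 to 19 with age over both sorts. The age difference of Il1r2 in DP cells was 2.30 to 2.98, and the correlations were 0.292 to 0.407 for the sort and 0.137 to 0.364 for age.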

Other observations

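The comparison of 24 with 3 months over both sorts and its tests, and the tests of the immunoglobulin profile, were chosen only after the result was seen. Setting the real grouping against other splits was planned, but the comparisons over both ages and over both sorts that were split were added afterwards. With age over both sorts 17 of 28 lists passed camera and 0 with an estimated correlation. All 16 B cell markers were higher at 24 months (median log2 0.80, camera adjusted p = 2.02e-05, adjusted p = 0.436 with an estimated correlation). So were plasma cell markers (0.73, 2.43e-04, adjusted p = 0.436 with an estimated correlation) and nuclear-encoded respiratory chain genes (0.24, 5.89e-05, adjusted p = 0.265 with an estimated correlation). Type 1 and cytotoxic genes were higher too (0.55, 2.43e-04, adjusted p = 0.436 with an estimated correlation), a call lost without both libraries numbered 2 (median 0.14, 0.0690). All 20 naive genes were lower (-0.91, camera adjusted p = 2.56e-06, adjusted p = 0.436 with an estimated correlation). Ribosomal genes were higher (0.13, 0.0125, adjusted p = 0.647 with an estimated correlation) and T cell receptor signalling genes lower (-0.35, 0.0403, adjusted p = 0.623 with an estimated correlation), and the direction of each turned under 1 of the other scalings. The ribosomal call was lost without DP_3mo 1 (median 0.00, 0.155), DN_3mo 1 (0.01, 0.0911), DN_3mo 3 (0.04, 0.236) or DN_24mo 2 (0.01, 0.456), and under 2 other alternatives. The T cell receptor call was lost without DP_3mo 1 (0.0529), DP_3mo unnumbered (0.102), DN_3mo 3 (0.203), DP_24mo 2 (0.0594), DP_24mo 3 (0.118) or DN_24mo 2 (0.225), and under 7 other alternatives. By limma 0 genes passed (smallest adjusted p = 0.784), and 930.0 had an unadjusted p under 0.05.

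Over both ages DP cells were higher in senescence genes (14 of 17, median log2 0.92, camera adjusted p = 3.75e-04, adjusted p = 0.281 with an estimated correlation), of which 7 rose when adjusted over the list alone. Among them were Spp1, the gene of the cytokine osteopontin (3.38, SE 0.75), and Cebpa, a myeloid transcription factor gene (2.68, SE 0.58). Chemokine receptor and homing genes did not move as a list (camera adjusted p = 0.664), though 5 members rose and 2 fell when adjusted over the list alone, with Cxcr3, a receptor of inflamed tissue homing, higher by 2.14. Cd68, a lysosomal gene of macrophages, was higher in DP cells (2.45, SE 0.49), while the macrophage list did not pass (0.587). The lists of interferon-stimulated (0.177), type 2 and type 17 (0.964), mitochondrially encoded (0.950), immediate early (0.411), dendritic cell (0.602) and platelet genes (0.597) did not pass camera over both ages either. The interferon-stimulated, mitochondrially encoded and immediate early lists differed between the libraries with few genes and the others. Their results therefore do not show that the sorts were alike in them. The 2 stromal and endothelial markers, Pecam1 among them, had a median of 0.51.

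Immunoglobulin variable genes of the 24-month libraries were alike in DP and DN cells of number 1 and, on the TPM scale, of number 2, while number 3 did not stand out. Across 186 segments, which are not independent replicates, DP and DN libraries correlated at 0.972 for number 1, 0.847 for number 2 and 0.181 for number 3, and other pairs at most at 0.573. On the log2 scale these were 0.869, 0.687 and 0.0987, with other pairs up to 0.675 and number 3 below both other pairs of DP_24mo 3 (0.204 and 0.169). Reads or RNA passed between the libraries of a pair were argued against, since Ly6c1 and Sostdc1 crossed at a ratio of at most 0.0220, against immunoglobulin ratios of 1.06 and 1.72. The matching by number was the 1 of 6 with the highest mean correlation (0.667, highest other 0.427, and 0.552, highest other 0.458, on the log2 scale), too few matchings to exclude chance, so one animal behind both libraries of a number stays open, as do a shared day of sorting and a biological difference, which were not tested.

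The real grouping was compared with other splits of the libraries. Over both ages 1 of 100 splits, the real one, called as many as 59 genes (highest other 22). Among the 28 splits that part as many pairs it was also the only one (highest other 14). This is a share under 0.05, but the comparison was added because no single age called a gene, so the splits do not exclude chance for this count. The 1548 genes at an unadjusted p under 0.05 were reached by 9 of 100 splits (highest other 2831), so chance could not be excluded there either. For lists 30 of 100 splits called as many as the 12 of the real one (highest other 17), and 4 of the 28 that part as many pairs (highest other 16), so chance could not be excluded. With age over both sorts all 100 splits called as many as the real 0 genes, which a count of 0 fixes beforehand and which says nothing about chance. The 7 drawn splits with all 4 libraries with few genes on one side called from 0 to 82 genes (median 7), and the other 93, the real one included, at most 4, which points to that structure without every such split showing it. For lists with age over both sorts 6 of 100 splits called as many as the real 17 (highest other 23), and chance could not be excluded. With 10 splits a share under 0.05 is out of reach: at 24 months 10 of 10 called as many genes as the real 0 (highest other 4), again fixed by the 0, and 5 of 10 as many lists as the real 12 (highest other 19). Among the 4 splits at 24 months that part as many pairs, only the real one reached 12 lists (highest other 10), too few splits to exclude chance. With age in DN cells these were 10 of 10 for the real 0 genes (highest other 5), fixed in the same way, and 3 of 10 for the real 12 lists (highest other 19).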
